A study of Mus musculus with 8 samples.

How the data were processed

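RNA sequencing of 8 mouse cecal tumors was used, 4 from the vehicle group and 4 from the tamoxifen group, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, explanted tumors were homogenized in Trizol, total RNA was purified on columns and libraries were made with standard Illumina protocols. The strandedness of the libraries and the length and number of reads are not given in the sources used here.

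The deposited table gives gene-level FPKM for each library, with a quantification status beside each value, in the layout of a Cuffdiff tracking table, per the file headers. Per the submitters' processing notes, the tools were STAR 2.3, Cufflinks and Cuffdiff and the genome build was mm9. Their roles, the annotation release, the scaling between libraries and the handling of reads that map to several places are not given in the sources used here. Confidence bounds in the deposited table were not used. All 8 libraries were matched to samples by the identifier in the sample description, and 0 columns were left unmapped. Gene symbols, identifiers and loci are those of the deposited table, with starts counted from 1.

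A total of 178 deposited values had a failed status and were listed at 0 FPKM. They were treated as missing, a choice made after the data were examined, and 48 tested genes had at least 1 such value. Rows with the same symbol were summed, which gave 34586 symbols. A gene was tested when its mean FPKM over the 8 libraries was at least 1 and each group had at least 2 estimates, which left 15023 genes. Values were transformed to log2(FPKM + 1), with no further scaling, so a log2 fold change understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p given for genes come from this test unless another is named. Means and SDs are of FPKM, and SEs are of the log2 fold change. Single values per library were compared with an exact 2-sided permutation test over all 70 arrangements of 4 against 4, whose smallest p is 0.0286.

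Before the data were examined, 24 gene lists were fixed for the tumor lineage, ERK output, cell cycle, smooth muscle, enteric neurons, glia, intestinal epithelium, T and NK cells, B and plasma cells, macrophages, neutrophils, mast cells, endothelium, fibroblasts and matrix, mesothelium, adipocytes, red blood cells, pancreatic acinar cells, skeletal muscle, interferon response, p53 response, immediate early genes, hypoxia and glycolysis, and oxidative phosphorylation. The 20 lists with at least 5 tested members were compared with all other tested genes by camera with a preset correlation of 0.01, using genes with no missing value, and adjusted over the 20 lists. With the correlation estimated from the data, 0 of the 8 lists past the threshold stayed past it. The fry test, which asks whether the genes of a list move 1 way on balance, passed 5 lists, and its mixed version, which asks whether they change in either direction, passed 12. For tissue composition, the mean log2 level of each of 14 cell type lists with at least 3 tested genes was compared between groups by the exact test.

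The genes named were fixed by a rule. It took Etv1, then Kit, Ano1, Gpr20, Dusp6, Spry4, Etv4, Etv5, Ccnd1 and Mki67 whatever their result. It then took the 12 largest rises and the 12 largest falls among genes past the threshold with no overlap between groups, leaving out predicted or clone-named genes and immunoglobulin or T cell receptor segments. From each list it took up to 4 members with the smallest p where the list passed and up to 2 otherwise. The rule gave 92 symbols, and some of them are not reported here. The loci of 9 of them overlap that of another gene at 1 FPKM or more, so their values are uncertain: Ccnd1, Cxcl10, Slc37a2, Cd34, Fcrla, Cd74, Egfl7, Tnnt3 and Car9.

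Depth per library is unknown. Relative depth was estimated from the FPKM that 1 read is worth in low genes and ranged 1.42-fold. The sum of 9 mitochondrial mRNAs was 23652 to 49439 FPKM per library, with no difference between groups on the log2 scale (exact permutation p = 0.714), nor did the median level of the tested genes differ (exact permutation p = 0.543). The procedure was tested on simulated data for 14975 genes with the levels and spread of tamoxifen against vehicle, of which 200 were changed. It recovered 56% of genes changed by 1 on the log2 scale and 92% of those changed by 2, and 5 of 153 calls, or 3.27%, were unchanged genes. The changed genes left out the lowest levels tested, and errors were independent between genes with the same spread in both groups. Correlation between genes and a wider spread in 1 group were therefore not simulated.

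Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.25 FPKM, no filter or a mean of at least 5 FPKM, scaling by the median ratio or to the same total (TPM), each row on its own, a block for the replicate number, a covariate for the 2 ranges of sample identifiers, a covariate for sex, robust and array-weighted limma, and leaving out each library in turn. Keeping failed estimates at 0 was added after the data were examined. The reference genome supplied was of another build and was not used.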

Results

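Gene expression was measured by RNA sequencing in 8 tumors explanted from the cecum of mice. The tumors are models of the gastrointestinal stromal tumor (GIST), a sarcoma related to the interstitial cells of Cajal, the pacemaker cells of the gut wall. The mice carried 1 mutant copy of Kit, loxP sites in both copies of Etv1 and a Cre recombinase that tamoxifen activates. The tumors gave 4 vehicle libraries and 4 tamoxifen libraries, and the comparison asks how the tumor transcriptome differs after Etv1 ablation. Values are gene-level FPKM (fragments mapped to a gene, scaled by the length of its transcripts and by the size of the library) for 37980 genes. Replicates carry different identifiers, but nothing states that they came from separate mice, so p-values measure the spread between these samples only.

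Absolute read depth is unknown, because only FPKM were used. The value of 1 read in low genes put the relative depth of the libraries between 0.822 and 1.16 of that of vehicle replicate 1, a 1.42-fold range, with no difference between groups (exact permutation p = 0.886). Each library had 14176 to 14841 gene symbols at 1 FPKM or more. The summed FPKM ran from 901764 to 1662240 per library, and 2 very short immunoglobulin segments, Ighj1 and Ighj4, held 5.42% to 54.6% of it. Libraries resembled each other within the vehicle group (Spearman correlation across genes 0.931 to 0.939 over 6 pairs) more than within the tamoxifen group (0.883 to 0.916). Between groups the correlation was 0.867 to 0.914 over 16 pairs. The first principal component held 27.4% of the variance and placed the vehicle libraries between -39.3 and -30.6 and the tamoxifen libraries between 18.2 and 57.4. Each group held 2 male and 2 female tumors, as judged from Xist and a Y-linked gene.

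Etv1, the floxed gene and an ETS transcription factor of the interstitial cells of Cajal, was lower on average after tamoxifen without passing the threshold. It measured 41.2 ± 7.03 FPKM in vehicle tumors and 25.8 ± 8.60 in tamoxifen tumors (SD, n = 4 each; exact permutation p = 0.0571). The log2 fold change of FPKM + 1 was -0.70 (SE 0.24, limma adjusted p = 0.13). The vehicle tumors measured 34.6, 51.1, 40.4 and 38.6 FPKM in replicates 1 to 4, and the tamoxifen tumors 34.9, 19.7, 31.4 and 17.4, so tamoxifen replicate 1 lay within the vehicle range. With libraries weighted by their quality the adjusted p was 0.049, against 0.0887 to 0.556 in the other alternatives. The gene (ENSMUSG00000004151, chromosome 12, 39505967 to 39594802 in mm9) has 1 row in the table, which covers exons inside and outside any deleted part.

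Of the 9 lineage, signalling and proliferation genes chosen before the data were examined, Ccnd1 alone passed the threshold. Ccnd1 encodes cyclin D1, which drives entry into the cell cycle. It fell from 38.5 ± 6.53 to 17.1 ± 8.89 FPKM (log2 fold change -1.22, SE 0.29, adjusted p = 0.0485, n = 4 each). That call was close to the threshold: it held without tamoxifen replicate 4 but was lost without any of the other 7 libraries in turn, with an adjusted p up to 0.133 without vehicle replicate 3. It was also lost in 7 of the 13 other alternatives, with an adjusted p of 0.05 to 0.108. The locus of Ccnd1 also overlaps that of the expressed gene Oraov1. Kit, the receptor tyrosine kinase mutated in these tumors (chromosome 5, 75970941 to 76052747), measured 760 ± 161 FPKM in vehicle and 447 ± 82.1 in tamoxifen tumors (log2 fold change -0.75, SE 0.20, adjusted p = 0.0674). Kit passed with sex as a covariate (adjusted p = 0.0427), with libraries weighted by quality (0.0438), without vehicle replicate 1 (0.0466) and without tamoxifen replicate 3 (0.049). Gpr20, an orphan receptor abundant in GIST, measured 150 ± 18.9 and 89.4 ± 31.4 FPKM (adjusted p = 0.0785), and passed with the range of the sample identifiers as a covariate (adjusted p = 0.0353), with libraries weighted by quality (0.0287) and without tamoxifen replicate 3 (0.0131). Ano1, the calcium-activated chloride channel used to diagnose GIST, measured 522 ± 83.4 and 433 ± 72.1 FPKM (adjusted p = 0.396). Dusp6 and Spry4, feedback inhibitors of ERK signalling, measured 110 ± 15.8 against 74.9 ± 11.4 FPKM (adjusted p = 0.0806) and 104 ± 24.4 against 65.2 ± 23.9 FPKM (adjusted p = 0.156). Dusp6 passed with libraries weighted by quality (adjusted p = 0.0494) and Spry4 without tamoxifen replicate 3 (0.046). The Etv1 relatives Etv4 (52.5 ± 6.55 against 38.6 ± 12.4 FPKM, adjusted p = 0.233) and Etv5 (28.1 ± 5.65 against 34.7 ± 11.1 FPKM, adjusted p = 0.524) did not pass. Neither did the proliferation marker Mki67 (6.28 ± 1.17 against 3.14 ± 1.89 FPKM, adjusted p = 0.114), except without tamoxifen replicate 4 (adjusted p = 0.0267).

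**Figure D1:**
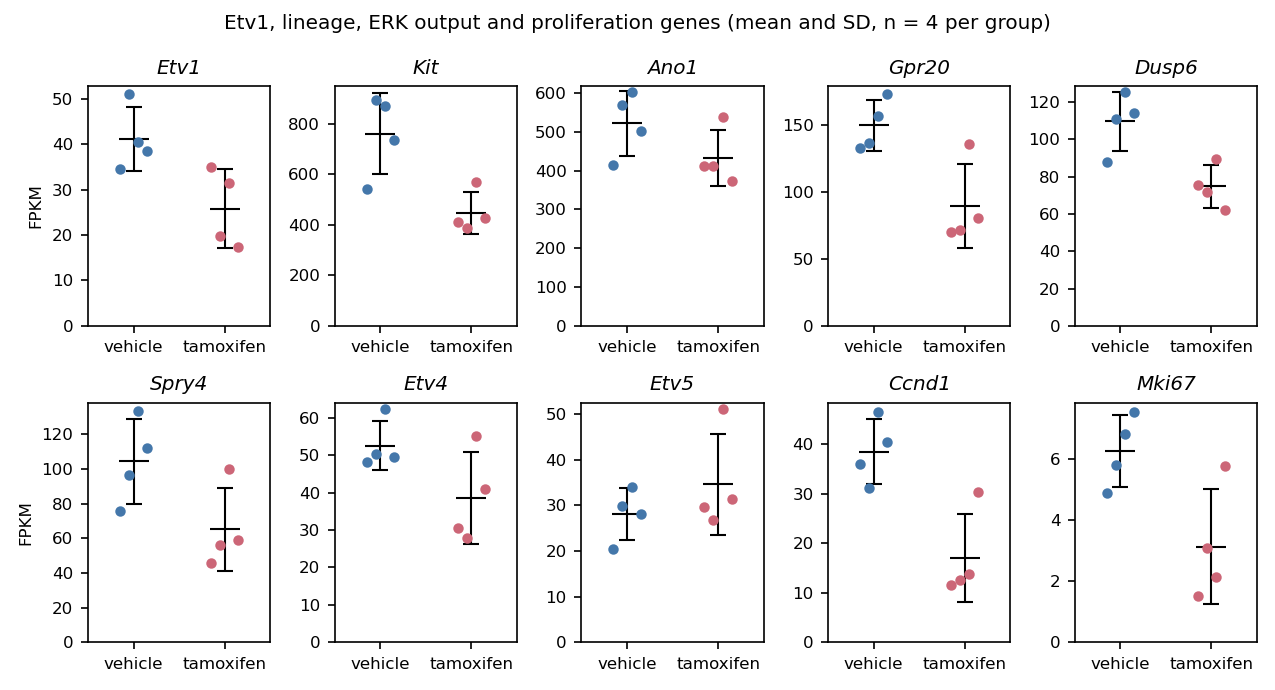
FPKM of Etv1 and the 9 other genes chosen before the data were examined, with 1 point per library and the mean and SD of each group (n = 4). The 4 tamoxifen values of Ccnd1 all lie below the 4 vehicle values, while Etv1 overlaps between groups through tamoxifen replicate 1 at 34.9 FPKM.

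The lists for the tumor lineage and for ERK output passed the mixed fry test, which takes no account of direction (adjusted p = 0.00267 and 1.55e-06). Under the main settings neither passed a test for a shared direction. Of 19 tested genes of the interstitial cell of Cajal and GIST lineage, 1 rose, 1 fell and 17 did not pass, or 2 and 5 when adjusted over the list alone. Edn3, an endothelin ligand, fell from 383 ± 75.3 to 187 ± 49.9 FPKM (log2 fold change -1.05, adjusted p = 0.0333), and Cd34, a surface protein of GIST and of endothelium, rose from 13.2 ± 1.53 to 22.7 ± 3.20 FPKM (log2 fold change 0.73, adjusted p = 0.024). The median change of the list was -0.16 (camera adjusted p = 0.125). Of 19 ERK output and feedback genes, 2 rose, 1 fell and 16 did not pass, or 2 and 4 when adjusted over the list alone. Plaur, the urokinase receptor, rose from 2.50 ± 0.579 to 13.0 ± 1.62 FPKM (log2 fold change 2.02, adjusted p = 0.00225), and the proto-oncogene Myc from 9.54 ± 0.253 to 15.7 ± 2.65 FPKM (log2 fold change 0.65, adjusted p = 0.0326). The median of this list was -0.04 while its mean was 0.04, and camera placed it upward with an adjusted p of 0.895. Leaving out 1 library ended the calls of Edn3 and Myc in 7 of 8 cases and of Cd34 in 5. In these fits the highest adjusted p was without vehicle replicate 3 (0.0903, 0.0948 and 0.0724). Scaling to the same total ended these calls too (adjusted p = 0.256, 0.208 and 0.167), as did the replicate block (0.0664, 0.0795 and 0.06).

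Across the transcriptome, 819 of 15023 tested genes differed between the groups, 358 higher and 461 lower after tamoxifen. Of these, 418 changed by at least 1 on the log2 scale, 204 upward and 214 downward. In all 819 the tamoxifen values did not overlap the vehicle values, with 4 values in each group except for 2 genes with 1 failed estimate each (Mir5107 and Chi3l3, named after their values were seen). Such separation occurred in 2270 tested genes, or 15.1%, where chance gives 2.86% with 4 values in each group. The count of genes called fell to 450, 288, 268 and 274 without vehicle replicates 1 to 4, and to 544 and 378 without tamoxifen replicates 1 and 2. Scaling every library to the same total FPKM, of which Ighj1 and Ighj4 are a large and variable part, called 221 genes, with 148 higher and 73 lower. Scaling by the median ratio called 843, with 366 higher and 477 lower.

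The 12 largest rises were led by Ly6g, a surface protein of neutrophils, which measured 1.96 ± 1.79 FPKM in vehicle and 147 ± 33.0 in tamoxifen tumors (log2 fold change 5.84, SE 0.45, adjusted p = 0.00225, n = 4 each; chromosome 15, 74987123 to 74989169). S100a8 and S100a9, the subunits of calprotectin, rose from 5.42 ± 2.87 to 108 ± 79.8 FPKM and from 4.26 ± 1.90 to 57.6 ± 39.7 FPKM. Some of the other rises were in genes of squamous or barrier epithelium, a grouping made after the values were seen. The protease inhibitor Csta rose from 0.258 ± 0.198 to 13.2 ± 5.27 FPKM (log2 fold change 3.43, SE 0.27, adjusted p = 0.00225), and the cornified envelope gene Sprr2h from 0.582 ± 0.567 to 16.8 ± 9.19 FPKM. The serine protease Prss22 rose from 0.0405 ± 0.0488 to 10.4 ± 7.32 FPKM, the annexin Anxa8 from 1.64 ± 0.861 to 25.1 ± 13.3 FPKM and S100a14 from 5.76 ± 2.02 to 59.5 ± 33.3 FPKM. Areg, the EGF receptor ligand amphiregulin, rose 13.4-fold, from 2.11 ± 1.12 to 28.4 ± 14.5 FPKM (adjusted p = 0.0074). Gpx3, a secreted glutathione peroxidase, rose from 31.0 ± 10.4 to 237 ± 98.3 FPKM, and Ang4, an antimicrobial angiogenin of Paneth and goblet cells, from 2.62 ± 1.95 to 30.1 ± 21.4 FPKM. AI747448 rose from 12.4 ± 11.2 to 112 ± 65.2 FPKM.

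The 12 largest falls were led by Cxcl9, an interferon-gamma-induced chemokine that attracts T cells. It fell 12.1-fold, from 500 ± 115 to 41.2 ± 5.77 FPKM (log2 fold change -3.55, SE 0.19, adjusted p = 0.00018, n = 4 each; chromosome 5, 92750357 to 92757105). Its relative Cxcl10 fell from 548 ± 404 to 62.9 ± 19.2 FPKM (adjusted p = 0.0239), at a locus that overlaps Art3 and Cxcl11. The interferon-inducible genes Gbp10 and Apol6 fell from 13.2 ± 3.51 to 1.34 ± 0.456 FPKM and from 412 ± 150 to 72.3 ± 19.7 FPKM. The MHC class II gene H2-Eb2 fell from 15.6 ± 4.63 to 2.11 ± 0.824 FPKM, and the serpin Serpina3f from 32.5 ± 16.5 to 5.19 ± 1.07 FPKM. Htr5b, a serotonin receptor gene, fell from 6.89 ± 1.12 to 0.0698 ± 0.0540 FPKM (log2 fold change -2.87, SE 0.15, adjusted p = 0.000177). Hao2, a peroxisomal hydroxyacid oxidase, fell from 20.7 ± 6.25 to 1.91 ± 2.00 FPKM, and the fetuin Fetub from 97.4 ± 27.9 to 14.6 ± 7.38 FPKM. Bpifb1 fell from 25.6 ± 6.17 to 4.17 ± 1.76 FPKM, and the sugar phosphate exchanger Slc37a2 from 28.2 ± 8.70 to 4.89 ± 2.22 FPKM. The beta-globin gene Hbb-b1 fell from 9.16 ± 4.46 to 0.381 ± 0.279 FPKM. Of these 24 genes, 21 stayed past the threshold without any 1 library. AI747448 lost its call without 6 of the 8 libraries (adjusted p up to 0.0978, without vehicle replicate 4). Ang4 lost it without vehicle replicates 3 and 4 and tamoxifen replicate 2 (0.0627, 0.0569 and 0.055). Cxcl10 lost it without vehicle replicate 2 and tamoxifen replicates 1 and 2 (0.0701, 0.0527 and 0.0611). The replicate block ended the calls of AI747448 (adjusted p = 0.0575), Ang4 (0.0586), Cxcl10 (0.0588) and Hao2 (0.0522). AI747448 also lost its call without a filter (0.0655), with sex as a covariate (0.0514) and with robust limma (0.0577). Ly6g, Sprr2h, Gbp10, Serpina3f, Apol6 and Hbb-b1 belong to families of similar genes whose reads the authors' counting could split, so their single values are uncertain.

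**Figure D2:**
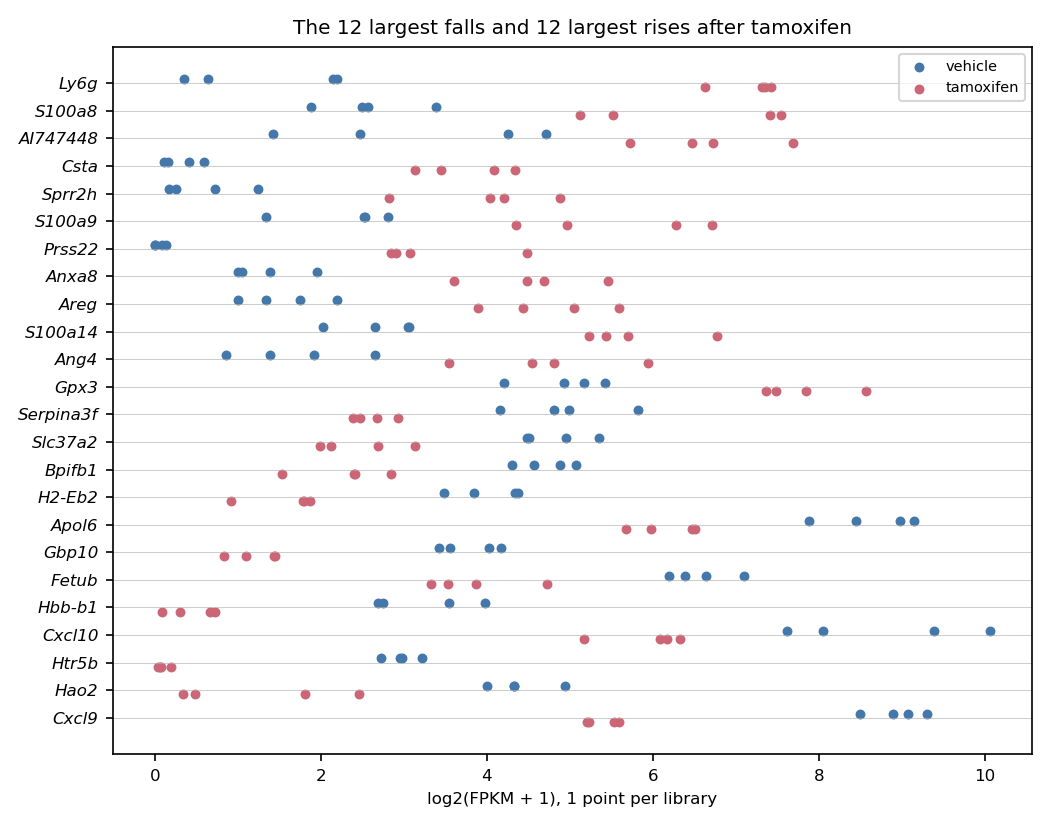
Values of the 12 genes with the largest rise and the 12 with the largest fall, as log2(FPKM + 1), with 1 point per library (4 vehicle, 4 tamoxifen). In each gene the groups do not overlap, from Ly6g with a log2 fold change of 5.84 to Cxcl9 with -3.55.

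All 18 interferon response genes had a negative change, and 9 fell past the threshold (15 when adjusted over the list alone), with a median log2 fold change of -1.19. The antiviral synthetase gene Oas2 fell from 61.8 ± 6.19 to 17.8 ± 3.50 FPKM (adjusted p = 0.00426) and the RNA sensor gene Ddx58 from 111 ± 22.2 to 48.7 ± 6.22 FPKM (adjusted p = 0.0118). All 16 T and NK cell genes also had a negative change and 10 fell (13 when adjusted over the list alone), with a median of -0.93. Cd3e, a chain of the T cell receptor complex, fell from 19.5 ± 2.94 to 8.38 ± 0.475 FPKM (log2 fold change -1.12, SE 0.12, adjusted p = 0.00653). The cytotoxic granule genes Nkg7 and Prf1 fell from 49.9 ± 6.36 to 18.8 ± 4.18 FPKM (adjusted p = 0.0074) and from 2.75 ± 0.106 to 0.947 ± 0.154 FPKM (adjusted p = 0.00952). Ddx58 and Prf1 lost their calls with scaling to the same total (adjusted p = 0.144 and 0.0874) and with the replicate block (0.0575 and 0.052).

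Other immune lists stand beside these falls. None of 10 B and plasma cell genes passed, although all 10 were lower (median -0.62, camera adjusted p = 0.0909). Fcrla measured 5.52 ± 3.69 against 2.10 ± 1.05 FPKM and Cd79a 9.43 ± 7.01 against 4.14 ± 2.57 FPKM. Of 16 macrophage and monocyte genes none passed (median 0.15, adjusted p = 0.373). Cd163, a scavenger receptor, measured 1.7 ± 0.390 against 5.99 ± 4.28 FPKM. Cd74, the MHC class II invariant chain, measured 3855 ± 553 (n = 3, with 1 failed estimate) against 1178 ± 606 FPKM (n = 4; adjusted p = 0.057). Cd74 passed with the range of the sample identifiers as a covariate (adjusted p = 0.0363), with robust limma (0.047), with libraries weighted by quality (0.0249) and without tamoxifen replicates 1 and 4 (0.0444 and 0.0344). Cd163 passed with libraries weighted by quality (0.0443) and Fcrla with the identifier covariate (0.0467). The camera test with a preset correlation placed the interferon list (adjusted p = 6.12e-14) and the T and NK cell list (1.06e-12) below other genes. Neither call held when the correlation was estimated (adjusted p = 0.321 and 0.27 with an estimated correlation), while fry gave adjusted p of 0.00393 and 0.00206. The per-library mean of the T and NK cell list was 4.07 ± 0.213 in vehicle and 3.13 ± 0.111 in tamoxifen tumors (log2 units, n = 4 each, exact permutation p = 0.0286, the smallest that 70 arrangements allow, and 0.1 when adjusted over 14 lists).

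None of 29 cell cycle genes passed the threshold, over all genes or over the list alone. A total of 28 of the 29 had a negative change, and the median was -0.61. The replication licensing genes Mcm2 and Mcm3 measured 12.4 ± 2.48 against 5.98 ± 2.40 FPKM (adjusted p = 0.0645) and 20.5 ± 4.10 against 10.8 ± 4.53 FPKM (adjusted p = 0.103). Ccne1, which encodes cyclin E1, measured 5.94 ± 0.961 against 3.01 ± 1.30 FPKM (adjusted p = 0.0688), and the spindle checkpoint gene Bub1b 9.63 ± 0.966 against 6.02 ± 1.79 FPKM (adjusted p = 0.0914). Without tamoxifen replicate 4, Mcm2, Ccne1 and Bub1b passed (adjusted p = 0.0342, 0.0214 and 0.0427). With libraries weighted by quality Mcm2, Ccne1 and Mcm3 passed (0.0299, 0.0406 and 0.0483), and with the range of the sample identifiers as a covariate Mcm2 and Mcm3 (0.0199 and 0.0405). The list was below other genes by camera with a preset correlation (adjusted p = 6.19e-08), a call lost when the correlation was estimated (0.613). The change of the list itself, tested against none by fry, did not pass (adjusted p = 0.128).

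Of 7 neutrophil genes 4 rose (5 when adjusted over the list alone), namely Ly6g, S100a8, S100a9 and Retnlg, with a list median of 2.27. Retnlg, a resistin-like secreted protein, rose from 0.641 ± 0.587 to 8.31 ± 6.03 FPKM (adjusted p = 0.0473). That call was lost without 7 of the 8 libraries, all but tamoxifen replicate 1, with an adjusted p up to 0.129 without vehicle replicate 3. The camera adjusted p was 0.000607, against 0.494 with an estimated correlation and 0.0246 by fry. Of 19 intestinal epithelium genes 1 rose (3 when adjusted over the list alone), the keratin Krt18, from 24.4 ± 5.91 to 79.0 ± 45.6 FPKM (adjusted p = 0.0391). Krt18 lost its call without 6 of the 8 libraries, with an adjusted p up to 0.109 without vehicle replicate 3. The keratins Krt19 (213 ± 38.4 against 447 ± 195 FPKM, adjusted p = 0.0744) and Krt20 (78.0 ± 34.8 against 198 ± 83.4 FPKM, adjusted p = 0.0607) did not pass. Krt20 passed without vehicle replicate 2 (adjusted p = 0.0493) and with libraries weighted by quality (0.0497). The colonic chloride exchanger Slc26a3 measured 51.9 ± 20.6 against 19.98 ± 14.1 FPKM (adjusted p = 0.0988), opposite in sign to the list median of 0.75, and passed without tamoxifen replicate 1 (adjusted p = 0.0365). The epithelial list had a camera adjusted p of 0.00129, an adjusted p of 0.63 with an estimated correlation and of 0.239 by fry.

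Of the endothelial, hypoxia and p53 lists 4 genes each rose, while 8 of 12, 13 of 17 and 12 of 16 members did not pass and 2, 7 and 5 had a negative change. Of 12 endothelial genes, Emcn (11.8 ± 0.931 to 23.7 ± 4.97 FPKM, adjusted p = 0.017), Egfl7 (38.8 ± 10.7 to 80.6 ± 8.82 FPKM, adjusted p = 0.0186), Pecam1 (17.5 ± 3.48 to 29.8 ± 3.29 FPKM, adjusted p = 0.0335) and Tek (2.61 ± 0.406 to 4.80 ± 0.971 FPKM, adjusted p = 0.0458) rose, and adjusted over the list alone 9 rose and 2 fell. The 2 that fell over the list alone, named after their values were seen, were Eng at 284 ± 79.1 against 154 ± 86.9 FPKM and Plvap at 113 ± 11.8 against 61.7 ± 24.5 FPKM. The list median was 0.68. Of 17 hypoxia and glycolysis genes, 4 rose (7 when adjusted over the list alone), with a median of 0.26. Vegfa, the endothelial growth factor, rose from 35.4 ± 4.93 to 94.4 ± 14.01 FPKM (log2 fold change 1.39, SE 0.16, adjusted p = 0.00653). Adm, the vasodilator adrenomedullin, rose from 1.65 ± 0.147 to 5.06 ± 0.707 FPKM (adjusted p = 0.00653). The mitophagy gene Bnip3 rose from 8.09 ± 1.23 to 15.0 ± 1.58 FPKM (adjusted p = 0.0146) and the carbonic anhydrase gene Car9 from 6.34 ± 1.88 to 20.5 ± 10.4 FPKM (adjusted p = 0.0497). Of 16 p53 response genes, 4 rose over all genes and over the list alone, with a median of 0.19. Plk2 rose from 2.26 ± 0.366 to 7.36 ± 2.19 FPKM (adjusted p = 0.0143) and the stress cytokine Gdf15 from 0.582 ± 0.237 to 2.10 ± 0.503 FPKM (adjusted p = 0.0241). The desmosome-associated gene Perp rose from 25.5 ± 6.84 to 69.1 ± 24.4 FPKM (adjusted p = 0.0335) and the cell cycle inhibitor Cdkn1a from 27.2 ± 2.07 to 51.6 ± 15.8 FPKM (adjusted p = 0.0483).

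The camera adjusted p with a preset correlation was 0.000607 for endothelium, 0.0064 for hypoxia and 0.0197 for p53. These calls were lost when the correlation was estimated (adjusted p = 0.494, 0.627 and 0.494), and the adjusted p was 0.0321, 0.128 and 0.0246 by fry. Without tamoxifen replicate 4 the hypoxia and p53 lists no longer passed (adjusted p = 0.145 and 0.08). Plk2, Adm, Vegfa and Bnip3 stayed past the threshold without any 1 library. Of the 8 libraries, leaving out 1 ended the call of Emcn in 2 cases, Egfl7 in 3, Gdf15 in 5, Pecam1 and Cdkn1a in 6, and Tek, Car9 and Perp in 7. Without vehicle replicate 3 the adjusted p was 0.0586 for Emcn, 0.0625 for Egfl7, 0.102 for Pecam1 and 0.131 for Tek. It was 0.13 for Car9, 0.0903 for Perp and 0.131 for Cdkn1a, each the highest of that gene in these fits. For Gdf15 the highest of these was 0.0674, without vehicle replicate 4. The same-total scaling ended the calls of Emcn (adjusted p = 0.0956), Pecam1 (0.17), Tek (0.236), Gdf15 (0.0998), Cdkn1a (0.147) and Bnip3 (0.144). The replicate block ended those calls as well (0.0589 to 0.0992), and those of Egfl7 and Perp (0.0592 and 0.0522).

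The remaining lists did not pass a test for a shared direction, while the mixed test passed smooth muscle, fibroblast and matrix, and adipocyte genes (adjusted p = 0.00299, 0.00788 and 0.0102). Of 14 smooth muscle genes 1 rose, Synpo2, an actin-binding protein, from 14.6 ± 2.68 to 35.1 ± 7.68 FPKM (adjusted p = 0.0122; list median 0.27, adjusted p = 0.0909). Acta2 measured 83.9 ± 23.8 against 117 ± 12.8 FPKM. None of 11 enteric neuron genes passed (median 0.38, adjusted p = 0.082), with the receptor gene Ret at 52.9 ± 16.7 against 27.0 ± 17.6 FPKM and Uchl1 at 8.73 ± 2.81 against 12.3 ± 0.622 FPKM. None of 7 glial genes passed (median 0.21, adjusted p = 0.373), Erbb3 measuring 8.94 ± 1.76 against 12.3 ± 3.95 FPKM and Cdh19 1.08 ± 0.547 against 2.18 ± 1.47 FPKM. Of 20 fibroblast and matrix genes 3 fell, or 4 with another 4 rising when adjusted over the list alone. The collagen gene Col5a2 fell from 89.8 ± 9.92 to 51.7 ± 9.14 FPKM (adjusted p = 0.0247), Thy1 from 41.2 ± 7.16 to 21.7 ± 5.06 FPKM (adjusted p = 0.0356) and Thbs2, named after its value was seen, from 150 ± 31.8 to 75.1 ± 22.0 FPKM (adjusted p = 0.0439). That list had a median of -0.08, a mean of 0.16 and a downward camera test (adjusted p = 0.895). None of 7 mesothelial genes passed (median 0.11, adjusted p = 0.858), Wt1 measuring 1.42 ± 0.477 against 3.80 ± 2.46 FPKM and Upk1b 2.25 ± 0.797 against 3.64 ± 1.79 FPKM. Of 7 adipocyte genes Pck1 fell from 3.01 ± 1.60 to 0.794 ± 0.132 FPKM (adjusted p = 0.0448; list median -0.71, adjusted p = 0.0909), while Fabp4 measured 57.4 ± 16.4 against 87.2 ± 15.2 FPKM. Of 16 immediate early genes Fos rose from 4.76 ± 1.05 to 13.3 ± 4.87 FPKM (adjusted p = 0.0378; list median -0.12, adjusted p = 0.895), and Dusp1 measured 12.7 ± 5.41 against 25.3 ± 3.73 FPKM. None of 23 oxidative phosphorylation genes passed (median -0.13, adjusted p = 0.118), with Sdhc at 345 ± 58.0 against 266 ± 31.4 FPKM.

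A further 4 marker lists had fewer than 5 tested genes and no list test. All 3 globin genes tested fell, Hbb-b1 as given above, Hba-a1 from 2.96 ± 0.912 to 0.104 ± 0.0857 FPKM and Hbb-b2, named after its value was seen, from 1.94 ± 1.29 to 0.0871 ± 0.0360 FPKM. Of 2 mast cell genes Gata2 rose from 0.793 ± 0.200 to 1.94 ± 0.348 FPKM (adjusted p = 0.0424) and Mcpt1 did not pass. Of 3 skeletal muscle genes Tnni2 rose from 2.53 ± 0.668 to 5.41 ± 0.565 FPKM (adjusted p = 0.0244), and Tnnt3 measured 7.78 ± 0.890 against 24.1 ± 15.1 FPKM. The acinar gene Cpb1 measured 2.37 ± 0.598 against 1.74 ± 0.312 FPKM. By the mean level per library, 4 of 14 tissue lists reached the smallest exact permutation p of 0.0286 (T and NK cell, neutrophil, globin and glia, the last with a difference of 0.20), and none passed when adjusted over the 14. The calls of Pck1 and Gata2 were lost whichever library was left out (adjusted p up to 0.0972 and 0.103). Those of Thy1 and Fos were lost without 7 of the 8 libraries (up to 0.0955 and 0.109). Those of Col5a2 and Tnni2 were lost without 4 (up to 0.0804 and 0.0684), while that of Synpo2 was kept without any 1 library. Scaling to the same total ended the calls of Synpo2 (adjusted p = 0.074), Col5a2 (0.305), Thy1 (0.0998), Tnni2 (0.0941), Pck1 (0.142) and Gata2 (0.222). The replicate block ended the calls of Synpo2 (adjusted p = 0.0522), Col5a2 (0.062), Thy1 (0.0872), Tnni2 (0.0779), Pck1 (0.0787), Gata2 (0.0913) and Fos (0.0561). Dusp1 passed with the range of the sample identifiers as a covariate (adjusted p = 0.0282), and Wt1 and Tnnt3 without tamoxifen replicate 3 (0.0443 and 0.0305).

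**Figure D3:**
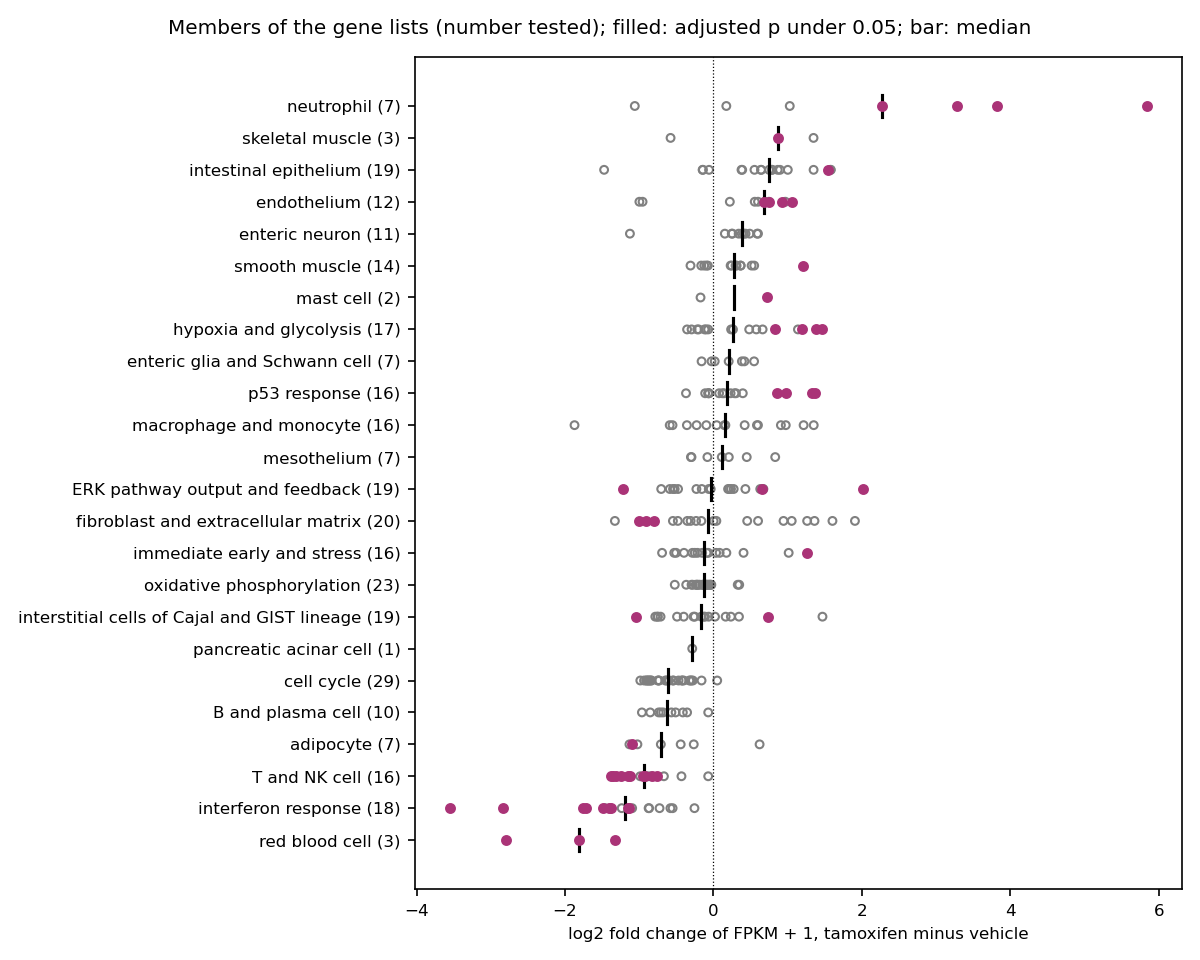
Log2 fold change of FPKM + 1 (tamoxifen minus vehicle) of every tested member of the 24 lists, with 1 point per gene, filled where the adjusted p was under 0.05, and a bar at the list median. The neutrophil list lies farthest up with a median of 2.27, and the interferon response and T and NK cell lists lie below 0 with medians of -1.19 and -0.93.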

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

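The count of splits of the libraries was fixed before the data were examined, while the tests of leukocyte share, sex, tamoxifen, mucosa, neutrophils, swapped labels and retained exons were chosen only after the results were seen. The real grouping called 819 genes and was 1 of 35 splits of the 8 libraries into 4 and 4 to call as many. The highest other count was 5, from a split that followed the sex of the mice. With 35 splits the smallest possible share is 1 of 35, so the count stood out but chance is not excluded. Splits that mix the groups also hold the group difference as spread, which lowers their counts.

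Interferon response genes and T and NK cell genes were lower after tamoxifen, by medians of -1.19 and -0.93, and 9 of 18 and 10 of 16 passed the threshold. The list calls did not hold in camera with an estimated correlation (adjusted p = 0.321 and 0.27). A smaller share of all leukocytes would lower macrophage genes alike, but the T and NK cell mean minus the macrophage mean was lower by -1.22 on the log2 scale in tamoxifen tumors (exact permutation p = 0.0286, the smallest possible). Both lists had been seen before this contrast was chosen, and the macrophage mean used 14 genes, without Cd74. All 10 B and plasma cell genes and all 9 markers of cross-presenting dendritic cells had a negative change, so a smaller share of some leukocytes stays open. Sex does not account for the fall of the interferon list, since its median was -1.31 among male and -1.12 among female tumors. An effect of tamoxifen apart from Etv1 cannot be told apart from Etv1 ablation, because 0 tamoxifen libraries came from mice with intact Etv1. Fewer T cells, less interferon signalling, or both may follow tamoxifen itself or Etv1 ablation. Whether T cells or interferon signalling moved first was not tested.

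Several genes of barrier or wounded epithelium, with Ly6g, S100a8 and S100a9, were higher after tamoxifen. Of 12 squamous and wound genes 8 passed the threshold, but of the 5 not looked at before the list was made only 1 did. In camera with an estimated correlation those 5 did not pass (adjusted p = 0.0916), nor did the neutrophil list (0.494). More mucosa in the dissected tissue would raise all epithelial genes alike, and the list medians cannot tell it apart from a change within epithelium. The intestinal epithelium list had a median of 0.75 (SD 0.73 over its genes). The 5 squamous and wound genes not looked at before their list was made had a median of 1.30. The epithelial genes did not all move alike, with 15 of 19 changes positive and 4 negative, but no fall passed the threshold. Larger rises, such as those of Csta and Sprr2h, were in genes picked by their rise, so they cannot decide. Neutrophil influx cannot be told apart from induction of these genes in other cells, because of 4 further neutrophil genes 2 were higher in every tamoxifen library and 2 were not. Mean FPKM was 0.0922 against 0.668 for Cxcr2 and 0.207 against 1.86 for Mmp8, but 4.23 against 5.60 for Csf3r and 8.90 against 3.59 for Mmp9. The values of Cxcr2 and Mmp8 were low. Ly6g did not track the other genes across the tamoxifen libraries. Tamoxifen replicate 1 had the highest Ly6g of its group (170 FPKM) but the lowest S100a8 (33.7), S100a9 (19.3), Cxcr2 (0.267) and Mmp8 (0.396). Csf3r was lowest in tamoxifen replicate 3 (1.78). A change of state in epithelium near the tumor may contribute, and this remains a hypothesis.

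Etv1 itself was lower by less than the threshold requires, with a log2 fold change of -0.70. Single libraries under the wrong label are argued against, since all 8 of 8 libraries lay on the side of their own label on a contrast made without that library. An exchange of the labels of the whole groups would give the same result, so the contrast cannot test it. Reads from exons that Cre leaves in place cannot be told apart from cells that kept Etv1, because the table has 1 row for the gene. Incomplete recombination and Etv1 from other cells of the tumor may contribute and were not tested.

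Among 205 groups of 4 libraries, 15 held a library far from the other 3, where chance gives about 10.25. Vehicle replicate 3 stood apart for Etv4 at 62.2 FPKM (others 48.1 to 50.2), Krt19 at 156 FPKM (226 to 238) and Wt1 at 2.13 FPKM (1.11 to 1.23). It was also low in the mean log2 level of the intestinal epithelium list at 5.77 (6.58 to 6.65) and of the T and NK cell list at 3.75 (4.15 to 4.20). Vehicle replicate 4 stood apart for Tek at 3.21 FPKM (2.35 to 2.48) and Cpb1 at 1.48 FPKM (2.57 to 2.75). Vehicle replicate 2 was apart for Emcn at 13.2 FPKM (11.3 to 11.5), and vehicle replicate 1 in the mean of the macrophage list at 5.82 (5.41 to 5.45). Tamoxifen replicate 4 was high for Prss22 at 21.3 FPKM (6.20 to 7.43), Krt18 at 147 FPKM (53.7 to 61.3) and Krt19 at 738 FPKM (333 to 381). Tamoxifen replicate 3 was low for Ly6g at 97.9 FPKM (158 to 170), tamoxifen replicate 2 was low for H2-Eb2 at 0.888 FPKM (2.44 to 2.66), and tamoxifen replicate 1 was high for Gdf15 at 2.85 FPKM (1.81 to 1.91).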

How the results depend on the processing

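No value of the genes named by the rule, the 20 fixed lists tested or the 14 tissue lists reversed under any alternative run for it. The lists chosen after the results were seen, and genes named only then, were not part of this check. All alternatives were planned except keeping failed estimates at 0, where 818 of the 819 genes called kept their direction. The other, Mir5107, named after its values were seen, went from -2.07 to 0.32 (adjusted p = 0.943) through 1 estimate listed as 0. The differences in tissue composition moved by less than the spread between replicates in all 140 recalculations, and the list tests kept their side of the threshold in 398, gained it in 22 and lost it in 14. The named genes kept their side in 1630, lost it in 226 and gained it in 31. Of 58 named genes past the threshold, 35 stayed past it without any 1 library, and 28 in every alternative that tested them. Requiring a mean of 5 FPKM called 534 genes, 207 of them higher, out of fewer genes tested, and the p53 list then had an adjusted p of 0.0689. Scaling to the same total (TPM) called 221 genes, 148 higher and 73 lower, so most were higher where most had been lower. Ighj1 and Ighj4 held 5.42% to 54.6% of the summed FPKM of a library, so that total depends strongly on them. Scaling by the median ratio called 843 genes, 366 higher and 477 lower, so most stayed lower there. With the same total, the camera adjusted p was 0.00924 for the B and plasma cell list and 0.016 for the adipocyte list. Array weights called 569 genes higher, gave an Etv1 log2 fold change of -0.81 (adjusted p = 0.049, against 0.0887 to 0.556 in the other alternatives), and list p of 0.0468 for smooth muscle, 0.0407 for macrophages and 0.0268 for oxidative phosphorylation. Without a filter, adjusted p were 0.0448 for the tumor lineage, 0.0249 for B and plasma cells, 0.0164 for adipocytes and 0.0366 for oxidative phosphorylation. With the identifier range as a covariate they were 0.00906 for B and plasma cells and 0.00347 for adipocytes. With an estimated correlation adjusted p were 0.613 for cell cycle, 0.63 for epithelium, 0.27 for T and NK cells, 0.494 for neutrophils, endothelium and p53, 0.321 for interferon and 0.627 for hypoxia. With fry, which tests a list against no change, they were 0.128 for cell cycle and hypoxia and 0.239 for epithelium. The replicate block called 252 genes, 113 higher and 139 lower, with an adjusted p of 0.00866 for the B and plasma cell list. Libraries with the same number correlated at -0.156, -0.00211, 0.145 and 0.0629 after removal of group means, against -0.145 to 0.151 for other pairs. Of the 4, 2 correlated best with their own number. So few pairs cannot decide whether the numbers pair the samples, and the labels do not state it. Leaving out 1 library at a time gave 268 to 856 genes called, 103 to 420 higher and 160 to 436 lower, with fewer samples in each fit. Adjusted p of lists then ranged from 0.00519 to 0.244 for smooth muscle, 0.00266 to 0.244 for enteric neurons, 0.000295 to 0.427 for B and plasma cells, 0.0396 to 0.897 for macrophages, 0.0411 to 0.23 for adipocytes, 0.0226 to 0.688 for oxidative phosphorylation, 0.00786 to 0.08 for p53 and 0.00153 to 0.145 for hypoxia. The 2 lost calls, p53 and hypoxia, were both without tamoxifen replicate 4. Except for fewer genes or samples, the cause was not tested. Robust limma was not run for list tests, since camera takes no such option. Absolute depth is unknown, so no limit of detection can be set for low genes.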

Other observations

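The 6 gene lists here were all chosen after the results were seen, and all were tested again on the members not looked at before. For MHC class I these were all 11. A member counted as looked at if it stood in the first listings of genes by p or by size of change. Cd74 of the fixed macrophage list therefore counts as not looked at among the class II genes. With its failed estimate it entered their median but not their list test. The second test is not independent, since the lists were made after the results. Antigen presentation genes were lower after tamoxifen. Of 11 MHC class II presentation genes, 7 fell and the median log2 fold change was -1.37 (camera adjusted p = 4.34e-10 over the 6 lists, 0.0491 with an estimated correlation). H2-Aa fell from 2385 ± 353 to 1069 ± 244 FPKM (adjusted p = 0.0167), H2-Eb1 from 1323 ± 174 to 554 ± 179 FPKM (adjusted p = 0.0234) and the peptide loading gene H2-DMa from 161 ± 12.1 to 51.5 ± 12.4 FPKM (adjusted p = 0.00653; n = 4 each). Of 11 MHC class I presentation genes, 7 fell (median -0.97, adjusted p = 5.24e-10, and 0.0469 with an estimated correlation), among them Nlrc5, the class I transactivator, from 69.9 ± 8.99 to 35.1 ± 3.76 FPKM (adjusted p = 0.00952). Of 14 interferon-inducible GTPases, 12 fell (median -1.49, adjusted p = 2.13e-15, and 0.0491 with an estimated correlation), with Igtp from 367 ± 101 to 106 ± 13.6 FPKM (adjusted p = 0.0074). Of 9 markers of cross-presenting dendritic cells, 4 fell (median -1.13, adjusted p = 2.75e-08, and 0.0469 with an estimated correlation), namely Batf3 from 15.8 ± 3.07 to 3.91 ± 1.03 FPKM (adjusted p = 0.00653), Clec9a from 9.73 ± 2.78 to 1.99 ± 0.919 FPKM (adjusted p = 0.00998), Xcr1 from 2.55 ± 0.774 to 0.495 ± 0.156 FPKM (adjusted p = 0.0158) and Itgae from 10.7 ± 2.41 to 3.86 ± 1.18 FPKM (adjusted p = 0.0184). Of the members not looked at before, 5 of 9 class II genes, 7 of 11 class I genes, 8 of 10 GTPases and 2 of 7 dendritic cell markers fell, with medians of -1.36, -0.97, -1.43 and -0.91. These passed with a preset correlation (adjusted p = 2.66e-07, 1.05e-09, 2.1e-10 and 1.41e-05) and did not with an estimated one (0.0818 each). For class I the genes were the same in both tests, and only the adjustment over the 6 lists differed. H2-Aa and H2-Ab1 share a locus in the table, as do Tap1 with Psmb9, Tap2 with Psmb8, Tgtp1 with Tgtp2 and Irf8 with Foxf1a. Reads could not be assigned without ambiguity there.

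Of 5 ligands tested, 4 rose (median 1.47, adjusted p = 4.56e-06, but 0.0536 with an estimated correlation). Besides Areg, Ereg rose from 0.247 ± 0.0655 to 4.07 ± 1.91 FPKM (adjusted p = 0.0117), Btc from 0.516 ± 0.141 to 3.44 ± 1.57 FPKM (adjusted p = 0.0247) and Hbegf from 1.85 ± 0.501 to 5.07 ± 1.57 FPKM (adjusted p = 0.0335), while Tgfa measured 1.90 ± 0.501 against 3.17 ± 1.09 FPKM (adjusted p = 0.248). The locus given for Btc is long (chromosome 5, 91701001 to 92631820), and its overlap with other genes was not checked. Of 12 squamous and wound genes, 8 rose (median 2.37, adjusted p = 1.3e-13, and 0.0469 with an estimated correlation). The laminin chain gene Lama3 rose from 1.79 ± 0.303 to 9.15 ± 4.30 FPKM (adjusted p = 0.0134), and the claudin gene Cldn4 from 6.13 ± 2.92 to 52.6 ± 27.3 FPKM (adjusted p = 0.00765). Of the members not looked at before, 2 of 3 ligands and 1 of 5 squamous genes rose, with medians of 1.07 and 1.30. These passed with a preset correlation (adjusted p = 0.00216 and 0.000111) and did not with an estimated one (0.0916 each). Within sexes, the squamous median was 2.06 among male and 2.68 among female tumors.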
